A study of Caenorhabditis elegans with 4 samples.

How the data were processed

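The samples are 4 RNA-seq libraries from whole young adult wild-type C. elegans, 2 from worms with the empty vector and 2 from worms with arf-1 RNAi, and the groups and replicate numbers were taken from the sample titles. Per the labels, total RNA was purified on columns and libraries were made and sequenced at a commercial service with standard Illumina protocols, and reads were analysed on the Dolphin platform. The aligner, the annotation and the tool versions are not given in the sources used here. The submitters' processing notes name RSEM, which assigns reads to transcripts, DESeq, and the ce11 genome build, none with a version. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

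The first deposited table holds FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, which the authors computed for 20499 genes with 2 decimals, and no read counts from it were used. The deposited FPKM are relative to the total of each library, so a rise in some abundant transcripts lowers all others. The column sums were 825400, 828039, 837451 and 814425 FPKM. The second deposited table is the authors' own differential expression result. Its values per library, a normalized signal in the deposited file, were in every gene equal to the FPKM of the first table cut to a whole number and multiplied by 1 constant per library (1.01, 0.998, 0.944 and 1.03), with a tolerance of 0.001. The p-values in the deposited table, its adjusted values and its −log10 p-values therefore come from whole-number FPKM rather than from read numbers in DESeq, as the deposited values show. The same deposited table gives a ratio (fold change) and a log2 fold change per gene, and 8423 genes have a line there, besides 219 blank lines. These deposited values are cited only as the authors' results.

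The planned design assumed read counts and named a test for that case, and it also named the alternative for other units, which was used since the table holds FPKM. Genes at 1 FPKM or more in at least 2 libraries were kept, a filter set once the unit was known. Values were transformed as log2(FPKM + 1), and limma 3.58.1 in R 4.3.3 fitted the group difference with an intensity trend and robust empirical Bayes moderation (residual df 2, median prior df 3.06), 2-sided, with Benjamini-Hochberg adjustment over the 13708 tested genes. A fold change is on the log2(FPKM + 1) scale, which understates the change of low genes, while ratios are those of the mean FPKM. At an unadjusted p under 0.05, 5067 genes passed, and at an FDR of 0.01, 427 did. Gene lists were fixed before the data were examined, 12 on immunity, ARF and Golgi traffic, ER stress and membrane lipids and 28 on tissues, stages, stress and housekeeping. Each list was tested with camera at a preset correlation of 0.01 between genes, which compares its members with all other genes, with Benjamini-Hochberg adjustment over the 12 and over the 28 lists separately. Camera with an estimated correlation and the directional rotation test fry, which asks whether the genes of a list move 1 way on balance, were alternatives. With an estimated correlation 0 of the 40 lists kept a call.

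The genes named follow a rule fixed before the data were examined. They are arf-1 and its relatives warf-1, arf-5 and arf-6, the 8 largest rises and 8 largest falls among called genes with separated groups and a mean of at least 5 FPKM, up to 3 called members of each of the 12 lists and up to 2 of each of the 28 lists where the list or at least 3 members passed, and 15 genes fixed by name. For the lists not all of these are printed. The planned limits, set for scaled read counts, were applied to FPKM. Other genes are named only where a count was 5 or fewer or where the text says so, and those were chosen after their values were seen. Gene names, positions and biotypes came from the Ensembl 115 annotation of WBcel235, the assembly also called ce11, with older names matched by sequence name and locus tag. Of the 20499 genes, 20239 were found in that annotation. Near-identical copies, such as the hsp-16.48, pud, major sperm protein and histone genes, can share reads, and their separate values are uncertain.

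Depth was estimated from the steps between low FPKM values of single-transcript genes, where 69.3% to 71.9% of the values fell within 0.15 of a whole fragment number. It was about 1.09e+07 to 1.19e+07 fragments per library, so that 1 FPKM on a transcript of 1 kb stands for about 11 to 12 fragments, and lower values rest on few fragments. Since the steps were not whole for nearly all genes, no read numbers were recovered and no model of read numbers was fitted. On data simulated from these libraries' means and spread, with 200 of 13708 genes changed, the limma test called 10.2% of 2-fold, 59.7% of 4-fold and 76.4% of 8-fold changes, and 5.26% of its calls were unchanged genes. In the same simulated comparison, 5 of 5 shifted lists and 0 of 5 unshifted lists were called at an unadjusted p under 0.05. Genes were simulated independently of each other, so this says nothing of lists whose genes move together. In that simulation most 2-fold changes were missed. The share missed in the data can differ, since 2240 genes passed there, which loosens the adjusted threshold compared with 200 changed genes.

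The alternatives were median-of-ratios, upper-quartile and equal-total scaling of the columns, no filter on low values, a non-robust fit, the 20 most abundant genes left out, the replicate number as a block, each library left out in turn, an FDR of 0.01 and a minimum change of 2-fold. Added after seeing the data were a minimum of 5 FPKM, pseudocounts of 0.1 and 5, FPKM cut to whole numbers, and columns scaled on body wall muscle and neuron genes. Figures and depth estimates were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.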

Results

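RNA-seq was carried out on whole young adult wild-type worms (Caenorhabditis elegans) subjected to RNAi against arf-1 or to the empty vector control of the RNAi feeding system. Each group held 2 libraries, 4 in all, and the single comparison of the series is arf-1 RNAi against empty vector. arf-1, the target named in the series, encodes an ARF small GTPase that recruits coat proteins to Golgi membranes. The comparison asks which genes, in particular genes of immunity, respond when it is depleted. Expression was given as FPKM for 20499 genes, of which 13708 reached 1 FPKM in at least 2 libraries and were tested. The depth was estimated from the steps between low FPKM values as about 1.17e+07 and 1.11e+07 fragments in the control libraries and 1.09e+07 and 1.19e+07 in the RNAi libraries. Genes at 1 FPKM or more numbered 12087 and 12024 in the controls and 13807 and 14286 after RNAi. Across genes, the log2 values of the 2 control libraries correlated at 0.984, those of the 2 RNAi libraries at 0.970, and libraries of different groups at 0.908 to 0.942.

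The targeted gene fell, and a relative with little signal in the controls rose above the level of arf-1 in the controls. arf-1 (WBGene00000182, chromosome III, 5714886 to 5717586, plus strand) was at 340 ± 29.7 FPKM (SD, n = 2) in the controls and 127 ± 26.6 FPKM after RNAi, a ratio of 0.373 (log2 change -1.43, SE 0.18, limma adjusted p = 0.0121). Both RNAi libraries lay below both controls, and the call was lost when either control library was left out, with an adjusted p of up to 0.0769. warf-1 (WBGene00000190, formerly arf-1.1, chromosome IV, 7634786 to 7635712), another ARF-type GTPase, rose from 2.36 ± 0.919 to 412 ± 31.2 FPKM, a ratio of 174 (log2 change 6.97, SE 0.22, limma adjusted p = 0.00173). The annotated pseudogene F20D1.5 (arl-7, WBGene00000191, chromosome X, 14980954 to 14981675) rose from 1.42 ± 0.467 to 60.8 ± 3.4 FPKM. arf-5, formerly arf-3, stood at 599 ± 30 and 516 ± 18.3 FPKM (limma adjusted p = 0.221), and arf-6 at 93.8 ± 3.67 and 84.6 ± 13.4 FPKM (limma adjusted p = 0.49). Of 12 tested ARF and ARF-like genes, 2 rose, 1 fell and 9 did not pass, with the same counts adjusted over the list alone. Their median log2 change of 0.13, which turned to -0.088 with median-of-ratios scaling, did not stand apart from other genes (camera adjusted p = 0.971). How reads were divided between these related sequences is not given in the sources used here, so their values are uncertain to that extent.

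**Figure D1:**
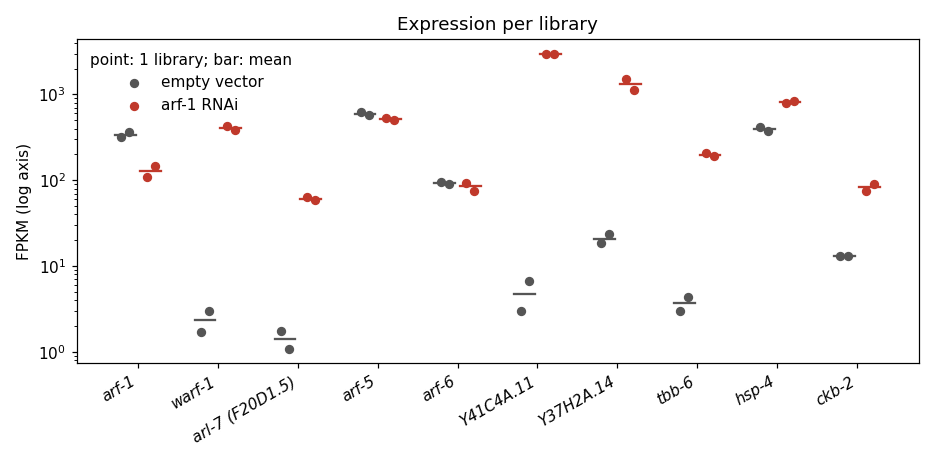
FPKM per library on a log axis for 10 genes, with grey points for the 2 empty vector libraries, red points for the 2 arf-1 RNAi libraries and bars at the group means. arf-1 fell from 340 to 127 FPKM, warf-1 rose from 2.36 to 412 FPKM, and arf-5 and arf-6 did not pass the test.

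Depletion of arf-1 was accompanied by broad changes, most of them rises. At a limma FDR of 0.05, 2240 genes changed, 1918 higher and 322 lower, and 1637 of the rises and 137 of the falls were at least 2-fold on the log2 scale. On the log2(FPKM + 1) scale, which limits low genes, the largest rise was that of Y41C4A.11, from 4.78 ± 2.58 to 2990 ± 4.86 FPKM (log2 change 9.09, SE 0.32, limma adjusted p = 0.00173). F22E5.6 was at 0.1 and 0 FPKM in the controls and at 185 and 154 FPKM after RNAi, and sdz-35 at 0.2 and 0.11 against 206 and 145 FPKM (log2 changes 7.34 and 7.23). By the ratio of mean FPKM both exceeded Y41C4A.11, at 3385 and 1131 against 626, on control values near 0. Y37H2A.14 rose 64-fold to 1335 ± 282 FPKM. tbb-6, a divergent beta-tubulin, rose 54.4-fold to 199 ± 9.12 FPKM. T26H5.9 rose 42.6-fold and asp-17, an aspartyl protease, rose 67.3-fold. The largest falls on that scale included the C-type lectins clec-222, from 53.7 ± 5.56 to 1.33 ± 0.0141 FPKM, clec-223, from 61.4 ± 16 to 1.77 ± 0.969 FPKM, and clec-190, from 19.7 ± 2.61 to 0.29 ± 0.099 FPKM. The cuticle collagen col-135 fell from 41.4 ± 8.12 to 0.81 ± 0.778 FPKM, F54F7.2 from 28.6 ± 2.11 to 0.5 ± 0.283 FPKM, and F45D11.14 was at a mean of 12 ± 0.68 FPKM in the controls and listed at 0 in both RNAi libraries. The pud genes, whose near-identical copies cannot be told apart with certainty, gave pud-1.2 (log2 change -4.47, SE 0.57) and pud-3 (log2 change -3.72, SE 0.56). T26H5.9 and pud-1.2 lost the call without RNAi replicate 2, and pud-3 lost it without either RNAi library, at adjusted p-values of up to 0.0715. Groups were separated, with every RNAi library on the same side of both controls, in 67.3% of the tested genes, against 33.3% by chance. The number of calls was 544 without control replicate 1, 515 without control replicate 2, 2721 without RNAi replicate 1 and 1154 without RNAi replicate 2. The split of calls moved with the scaling: 85.6% were higher with the FPKM columns as deposited, 59.1% (1537 higher, 1065 lower) with median-of-ratios scaling and 52.4% (1467 higher, 1330 lower) with columns scaled on body wall muscle and neuron genes. With upper-quartile scaling 78.9% were higher (1568 higher, 419 lower). The median log2 change over all tested genes was 0.21 as deposited, 0.014 with median-of-ratios, 0.15 with upper-quartile and -0.29 with muscle and neuron scaling. Counts of higher and lower genes per list also move with these scalings and are given below for both median-of-ratios and muscle and neuron scaling where they differ much. Medians of called lists of immunity and ER genes are therefore also given relative to it.

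Genes of several branches of innate immunity rose together. Of 10 tested infection-response genes known to be induced independently of the PMK-1 p38 kinase, 8 rose and 2 did not pass (adjusted over the list alone, 8 rose and 1 fell). They included C25F9.11, from 1.73 ± 0.969 to 30.1 ± 3.95 FPKM, rcd-1, from 0.225 ± 0.191 to 10.2 ± 1.63 FPKM, and gst-38, from 0.365 ± 0.0919 to 8.83 ± 0.509 FPKM. The heat shock, glutathione transferase and UDP-glycosyltransferase lists each share 1 tested gene with this list, which is gst-38 for the glutathione transferases. irg-1, a target of the ZIP-2 transcription factor, rose from 1.48 ± 0.771 to 12.7 ± 4.36 FPKM (limma adjusted p = 0.0173), a call lost without control replicate 1 at 0.0626. The list median was a log2 change of 2.18, which was 1.98 above that of all tested genes (camera adjusted p = 0.00253, or adjusted p = 0.271 with an estimated correlation). CUB-like and dod genes, which encode secreted proteins linked to infection, gave 11 of 21 higher and 0 lower, with 10 not passing (adjusted over the list alone, 14 rose). Their median was 1.41, which was 1.2 above all genes (camera adjusted p = 0.000722, or adjusted p = 0.271 with an estimated correlation). irg-8 rose from 203 ± 18.8 to 896 ± 21.1 FPKM, dod-19 rose 4.24-fold to 477 ± 75.7 FPKM and cld-9 from 3.28 ± 0.184 to 18.3 ± 1.81 FPKM. The epidermal antimicrobial peptides of the nlp and cnc families rose in 12 of 16 members and fell in 0, with 4 not passing (adjusted over the list alone, 13 rose). Their median was 1.75, which was 1.55 above all genes (camera adjusted p = 0.000362, or adjusted p = 0.271 with an estimated correlation). nlp-34 rose 25.4-fold, cnc-2 rose 20.8-fold, nlp-31 rose 4.97-fold and nlp-29 rose 3.39-fold. The nlp-29 call was lost without control replicate 2 or either RNAi library, at an adjusted p of up to 0.0815. The intracellular pathogen response, a program induced by viruses and microsporidia, rose in 10 of 24 genes with 14 not passing (adjusted over the list alone, 14 rose). Their median was 1.05, which was 0.84 above all genes (camera adjusted p = 0.000848, or adjusted p = 0.271 with an estimated correlation, and lost at 0.0577 with no filter on low values). The SCF ubiquitin ligase components skr-3, skr-4 and skr-5 rose 6.13-fold, 7.14-fold and 25.9-fold. pals-5 was at 0 and 0.5 FPKM in the controls, listed at 0 after RNAi and not tested. Under muscle and neuron scaling the 4 lists gave 7, 11, 11 and 8 higher, with 1, 0, 1 and 0 lower.

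Some PMK-1 p38-dependent genes rose. 6 of 14 rose, 0 fell and 8 did not pass (the same counts adjusted over the list alone; 5 higher and 1 lower with muscle and neuron scaling), and 9 of the 14 are also in the CUB-like list. Their median log2 change was 0.82 (camera adjusted p = 0.0836). The p38-dependent set passed without control replicate 2 at 0.00508, with median-of-ratios scaling at 0.0367 and with muscle and neuron scaling at 0.0273, and its adjusted p was 0.393 with an estimated correlation. catp-3 rose from 2.28 ± 1.8 to 22.2 ± 3.51 FPKM and irg-4 from 1.56 ± 0.0707 to 9.88 ± 1.93 FPKM, while irg-5 rose 4.36-fold from 2.7 ± 1.4 FPKM. catp-3 lost the call without RNAi replicate 2. irg-4 and irg-5 lost the call when either control was left out, and irg-5 also without either RNAi library, at an adjusted p of up to 0.133. sysm-1 was at 45.4 and 2.16 FPKM in the 2 controls and at 12.9 and 6.74 FPKM after RNAi (limma adjusted p = 0.916). The controls also differed in dod-24, named after its values were seen, at 4.37 and 74.4 FPKM against 9.4 and 12.2 FPKM after RNAi (limma adjusted p = 0.675). C-type lectins moved both ways, with 13 of 89 higher, 12 lower and 64 not passing (adjusted over the list alone, 22 rose and 17 fell). With median-of-ratios scaling 12 were higher and 15 lower, and with muscle and neuron scaling 10 and 26. Genes of the clec stem were enriched among the falls (exact hypergeometric test, Benjamini-Hochberg adjusted p = 9.92e-05) and not among the rises (unadjusted p = 0.272). Their median log2 change was 0.13, or -0.064 with median-of-ratios scaling. The set test, which compares the list with all other genes, pointed downward (camera adjusted p = 0.11, and 0.0398 without control replicate 2). Among 33 lysozymes and saposin-like genes, 8 rose, 1 fell and 24 did not pass (adjusted over the list alone, 11 rose and 1 fell), with a median of 0.53 (camera adjusted p = 0.469, and 0.040 without control replicate 1). Scaled on muscle and neuron genes, 8 were higher and 5 lower. ilys-5 fell from 926 ± 134 to 405 ± 26.3 FPKM, and ilys-2 rose from 0.855 ± 0.445 to 6.83 ± 0.997 FPKM, although the ilys-2 call was lost without either control and the ilys-5 call without control replicate 2.

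Genes of folding in the endoplasmic reticulum rose as a group. Of 28 tested genes of the ER unfolded protein response and ER folding, 17 rose, 0 fell and 11 did not pass (adjusted over the list alone, 20 rose). Their median was 0.67, which was 0.46 above all genes (camera adjusted p = 1.62e-05, or adjusted p = 0.271 with an estimated correlation). The BiP chaperone hsp-4 rose from 394 ± 26.1 to 811 ± 25.8 FPKM (log2 change 1.04, SE 0.11, limma adjusted p = 0.0086), a call lost without either control (adjusted p up to 0.0678). pdi-6, a protein disulfide isomerase, rose from 143 ± 2.46 to 369 ± 15.3 FPKM and dnj-7, the ER co-chaperone P58IPK, from 24 ± 0.969 to 60.4 ± 1.43 FPKM. With median-of-ratios scaling 11 of the 28 passed, and scaled on muscle and neuron genes 2 passed and the median was 0.18. The COPI coat and ARF regulators gave 5 of 18 higher and 13 not passing (adjusted over the list alone, 8 rose), with a median of 0.38 that turned to -0.11 with 0 calls when scaled on muscle and neuron genes (2 calls with median-of-ratios scaling). Their set test gave a camera adjusted p = 0.0149 (adjusted p = 0.271 with an estimated correlation). It was lost with median-of-ratios scaling at 0.14, with muscle and neuron scaling at 0.857 and without control replicate 1 or 2 at 0.0525 and 0.0522. erd-2.1, the receptor that retrieves ER proteins from the Golgi, rose from 31.1 ± 0.304 to 79.8 ± 0.0566 FPKM. gbf-1, an ARF exchange factor, rose from 56.8 ± 5.31 to 115 ± 0.99 FPKM and copd-1, a COPI subunit, from 94.2 ± 2.19 to 148 ± 3.06 FPKM. Both calls were lost without either control, at an adjusted p of up to 0.167. Of 28 COPII, Golgi SNARE and golgin genes, 2 rose and 26 did not pass, also when adjusted over the list alone. The median of 0.17 turned to -0.047 with median-of-ratios scaling (camera adjusted p = 0.325). The SNARE gene sec-22 rose from 13.2 ± 2.42 to 71.6 ± 0.566 FPKM. sec-23, a COPII coat subunit, rose from 74.2 ± 5.17 to 133 ± 21.2 FPKM, a call lost in 8 of the fits tried, including those without either control or RNAi replicate 2 (adjusted p up to 0.165). Across fits with the preset correlation, camera adjusted p-values of the 6 called lists of immunity, ER and traffic genes ranged from 3.83e-07 to 0.857. The highest value was that of the COPI list. Of the 6 lists, 4 kept the call under every such fit, and the COPI and intracellular pathogen response lists did not. With an estimated correlation all 6 lost it.

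Among 39 genes of phosphatidylcholine synthesis, the methionine cycle and lipogenesis, 11 rose, 0 fell and 28 did not pass (adjusted over the list alone, 14 rose). The median was 0.42, or -0.079 when scaled on muscle and neuron genes. The set test did not pass (camera adjusted p = 0.0501), although it passed without either control or RNAi replicate 1, at 0.0137 to 0.0398. With median-of-ratios scaling 7 rose and 1 fell, and with muscle and neuron scaling 4 and 1. The choline kinase ckb-2, which is also in the ER list, rose from 13 ± 0.0283 to 82.8 ± 9.85 FPKM (log2 change 2.58, SE 0.14, limma adjusted p = 0.00296). The fatty acid desaturase fat-2 rose from 482 ± 43.6 to 1253 ± 91.8 FPKM. pcyt-1, the rate-limiting enzyme of the CDP-choline route, rose from 20.8 ± 1.82 to 52.4 ± 2.6 FPKM, a call lost without control replicate 1 at 0.0543. sbp-1, the SREBP ortholog, rose from 6.22 ± 0.113 to 13.6 ± 0.262 FPKM, a call lost when any of the 4 libraries was left out (adjusted p up to 0.124). fat-7 was at 18.2 ± 14.3 and 36.7 ± 1.09 FPKM (limma adjusted p = 0.182). sams-1, which makes S-adenosylmethionine, was at 174 ± 59.3 and 187 ± 47.1 FPKM (limma adjusted p = 0.794). pmt-2, a phosphatidylcholine-synthesis methyltransferase, was at 210 ± 9.85 and 242 ± 49.8 FPKM (limma adjusted p = 0.465). The CREB-like gene crh-2 was at 110 ± 8.53 and 113 ± 0.0354 FPKM (limma adjusted p = 0.857).

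**Figure D2:**
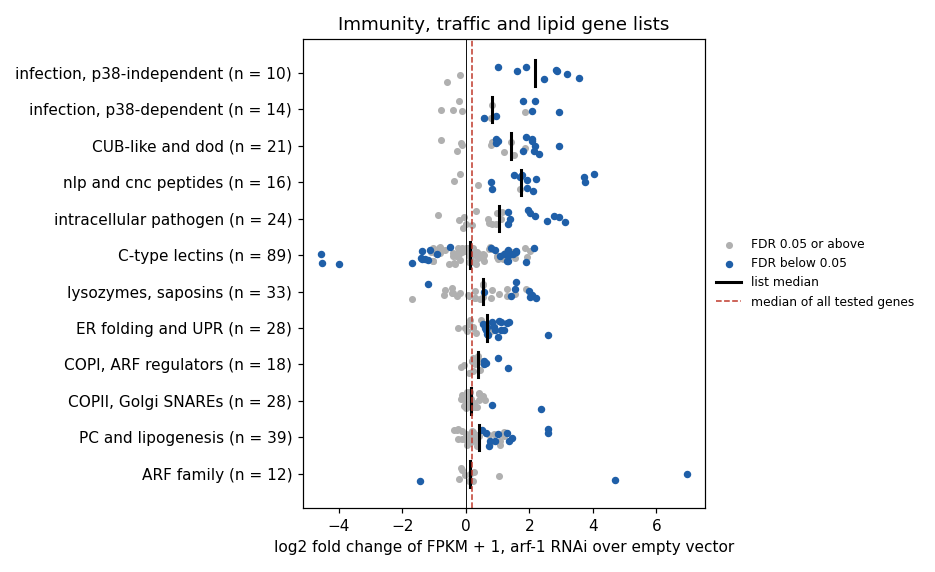
Log2 fold change (log2 of FPKM + 1, arf-1 RNAi over empty vector) of each tested gene in 12 gene lists, with blue points past an FDR of 0.05, black bars at list medians and a dashed line at the median of all tested genes, 0.21. The median of the p38-independent infection genes was 2.18 and that of the C-type lectins 0.13, with 13 lectins higher and 12 lower (10 and 26 with muscle and neuron scaling).

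Markers of tissues and stages also moved. Oocyte and eggshell genes fell in 20 of 35 cases and rose in 0, with 15 not passing (adjusted over the list alone, 31 fell). Their median was -0.54 (camera adjusted p = 4.23e-21, or adjusted p = 0.446 with an estimated correlation). perm-4, an eggshell permeability barrier protein, fell 3.02-fold from 1549 ± 343 FPKM and the eggshell protein gene cbd-1 from 577 ± 11 to 342 ± 4.03 FPKM. Germ cell and meiosis genes fell in 7 of 34 cases with 27 not passing (8 adjusted over the list alone, median -0.26, camera adjusted p = 4.14e-09, or adjusted p = 0.446 with an estimated correlation), among them cgh-1 and glh-2. DNA replication and cell division genes fell in 11 of 34 with 23 not passing (13 adjusted over the list alone, median -0.32, camera adjusted p = 8e-14, or adjusted p = 0.446 with an estimated correlation), among them rnr-1 and mcm-6. The calls of cbd-1, cgh-1, glh-2, rnr-1 and mcm-6 were lost without either control, and those of cgh-1 and mcm-6 also without RNAi replicate 2, at an adjusted p of up to 0.19. In these 3 lists, 31, 11 and 20 genes were lower with median-of-ratios scaling and 33, 14 and 17 with muscle and neuron scaling, with 0 higher. Sperm genes rose in 34 of 52 cases, with 1 lower and 17 not passing (adjusted over the list alone, 46 rose and 1 fell). Their median was 2.35 (camera adjusted p = 3.43e-09, or adjusted p = 0.659 with an estimated correlation), and 32 were higher with median-of-ratios and 44 with muscle and neuron scaling. Examples are ssp-35 and nspd-1, whose calls were lost without control replicate 2 at 0.0535 and without RNAi replicate 2 at 0.0586. Many are near-identical copies of major sperm protein genes whose separate values are uncertain. The median sperm gene was 1.21 higher on the log2 scale in RNAi replicate 2 than in RNAi replicate 1, and 0.6 lower in control replicate 2 than in control replicate 1.

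Some cuticle and molting genes rose, and their levels differed between the RNAi libraries. Of 124 cuticle collagens, 20 rose, 2 fell and 102 did not pass (adjusted over the list alone, 68 rose and 2 fell), with a median of 1.71 (camera adjusted p = 2.4e-05, or adjusted p = 0.666 with an estimated correlation). The count of collagens moved with the scaling, with 16 higher and 3 lower under median-of-ratios, 10 and 2 under upper-quartile and 61 and 7 under muscle and neuron scaling. As deposited, the share called higher was 16% against 14% of all tested genes, and 12 of 106 genes with the col stem were higher (exact hypergeometric test, p = 0.638). dpy-7, a furrow collagen, rose from 0.56 ± 0.339 to 5.81 ± 0.354 FPKM and the strut collagen bli-2 from 0.95 ± 0.141 to 12.9 ± 8.95 FPKM. Both calls were lost without either control, at an adjusted p of up to 0.12. Larval molting genes rose in 11 of 28 cases with 17 not passing (18 adjusted over the list alone, median 1.31, camera adjusted p = 0.00063, or adjusted p = 0.632 with an estimated correlation). They included noah-1, from 1.4 ± 0.0354 to 9.35 ± 1.15 FPKM, and wrt-10, from 2.02 ± 0.113 to 17.9 ± 6.17 FPKM. The noah-1 call was lost without control replicate 2 at 0.052. Adult epidermis markers, 14 of which are collagens, gave 5 of 15 higher and 10 not passing (12 higher adjusted over the list alone, median 2.39, camera adjusted p = 0.00444). Pharyngeal cuticle genes gave 4 of 18 higher and 14 not passing (13 higher adjusted over the list alone, median 2.05, camera adjusted p = 0.00129). Both lists had an adjusted p = 0.659 with an estimated correlation. Epidermis markers gave 4 higher with median-of-ratios and 12 with muscle and neuron scaling, and pharyngeal cuticle genes 2 and 11. The median was higher in RNAi replicate 2 than in RNAi replicate 1 by 1.41 for collagens, 0.42 for molting genes, 1.66 for epidermis markers and 1.67 for pharyngeal cuticle genes.

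Pan-neuronal and pharynx genes rose in part, while muscle, intestine and yolk lists did not pass their set tests. Pan-neuronal genes rose in 8 of 30 cases with 22 not passing (12 adjusted over the list alone, median 0.55, camera adjusted p = 0.00727, or adjusted p = 0.659 with an estimated correlation). The syntaxin unc-64 rose from 18 ± 1.46 to 55.4 ± 5.2 FPKM and unc-18 from 22.6 ± 1.14 to 47.7 ± 3.22 FPKM, the latter call being lost without either control (adjusted p up to 0.0798). Pharynx genes rose in 4 of 17 cases with 13 not passing (5 adjusted over the list alone, median 0.75, camera adjusted p = 0.0306, or adjusted p = 0.659 with an estimated correlation), among them the troponin C gene tnc-2, whose call was lost without control replicate 1 at 0.0588. The set calls of neurons and pharynx were lost without control replicate 1, at 0.0519 and 0.0942, and without RNAi replicate 2, at 0.12 and 0.165. With median-of-ratios scaling 6 neuron genes were higher and 2 lower, and 1 pharynx gene was higher. The pharynx call was also lost with whole-number FPKM at 0.0828 and with muscle and neuron scaling at 0.114. Under the latter, neuron genes gave 2 higher and 1 lower and lost the set call at 0.24, but that scaling centres them by construction. Intestinal genes gave 9 of 27 higher, 1 lower and 17 not passing (adjusted over the list alone, 13 rose and 2 fell; median 0.67, camera adjusted p = 0.0705). The GATA factor elt-2 rose from 3.54 ± 0.0354 to 17.8 ± 1.42 FPKM. The intestinal set passed without control replicate 1 at 0.00866 and without RNAi replicate 1 at 0.0212, with median-of-ratios scaling at 0.0302, with no filter at 0.0496 and with a minimum of 5 FPKM at 0.0274. Intestinal genes gave 4 higher and 4 lower with muscle and neuron scaling. Body wall muscle genes gave 1 of 26 higher and 25 not passing (0 adjusted over the list alone, median 0.45, or -0.042 when scaled on muscle and neuron genes, which centres this list by construction). Their camera adjusted p was 0.141 (0.00159 without control replicate 2 and 0.0148 without RNAi replicate 1). Of 6 vitellogenins, which encode yolk, vit-2 rose from 1083 ± 357 to 2243 ± 54.1 FPKM (limma adjusted p = 0.0421) and 5 did not pass (1 higher adjusted over the list alone). The vitellogenin list had a median of -0.49 (camera adjusted p = 0.358, or 0.00134 without control replicate 2), with 0 higher and 2 lower under muscle and neuron scaling. The vit-2 call was lost in 10 of the fits tried, including those without control replicate 2 or either RNAi library (adjusted p up to 0.122), and the vitellogenin median was lower by 1.56 on the log2 scale in control replicate 2 than in control replicate 1. Ribosomal protein genes had a median of -0.25 with 1 higher and 1 lower of 81 and 79 not passing (camera adjusted p = 7.4e-12, or adjusted p = 0.48 with an estimated correlation). Proteasome genes had a median of -0.28 with 0 of 36 past the test (camera adjusted p = 3.71e-11, or adjusted p = 0.468 with an estimated correlation). Adjusted over the list alone, 0 members of either list passed. Lower ribosomal protein genes numbered 8 with median-of-ratios and 56 with muscle and neuron scaling, and lower proteasome genes 16 and 18. rpl-25.1 rose 2.06-fold while its paralog rpl-25.2 fell by 0.51 on the log2 scale. Both calls were lost without either control or RNAi replicate 2, and that of rpl-25.2 also without RNAi replicate 1, at an adjusted p of up to 0.213. Histone genes gave 1 of 55 higher, 3 lower and 51 not passing (0 adjusted over the list alone, median -0.31, camera adjusted p = 0.00129, or adjusted p = 0.659 with an estimated correlation). With muscle and neuron scaling 5 were higher and 18 lower. The set call was lost without control replicate 1 at 0.555 and with median-of-ratios scaling at 0.0547 and with a minimum of 5 FPKM at 0.212, and histone genes share near-identical sequences.

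**Figure D3:**
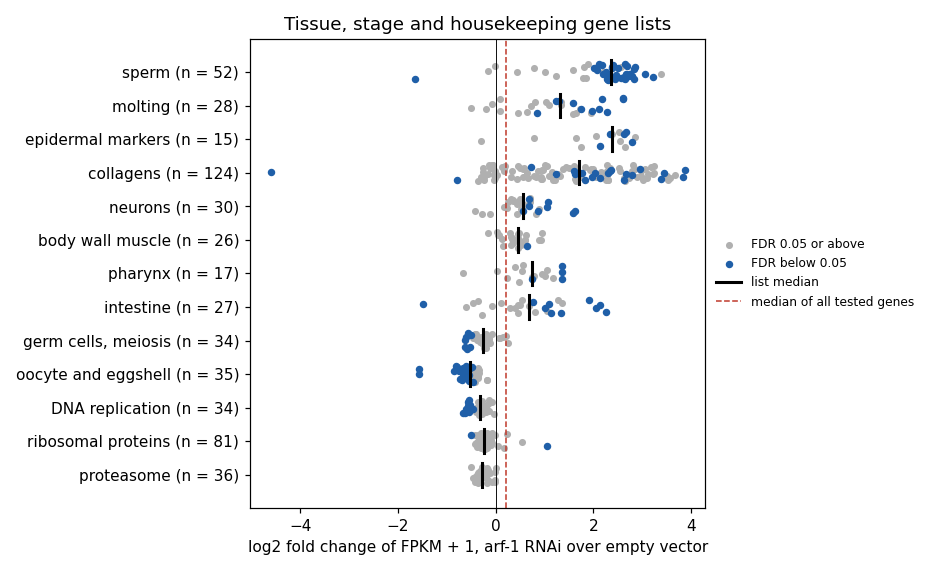
Log2 fold change (log2 of FPKM + 1, arf-1 RNAi over empty vector) of each tested gene in 13 tissue, stage and housekeeping lists, with blue points past an FDR of 0.05, black bars at list medians and a dashed line at the median of all tested genes, 0.21. Sperm genes had a median of 2.35, oocyte and eggshell genes -0.54 and proteasome genes -0.28.

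Stress genes showed opposite movements within a family. Among 20 cytosolic heat shock genes, 9 rose, 4 fell and 7 did not pass (adjusted over the list alone, 11 rose and 5 fell; median 0.97, camera adjusted p = 0.341). Scaled on muscle and neuron genes, 6 were higher and 6 lower, and the set passed at 0.00944. Both annotated copies of hsp-16.48 were listed with the same values, 8.75 ± 0.721 FPKM in the controls and 175 ± 57.6 FPKM after RNAi, so they count as 1 measurement. The 4 members that fell were hsp-1 (log2 change -0.56), hsp-90 (-0.61), hsp-110 (-0.77) and dnj-13 (-0.56), named after their values were seen because the count is small. Mitochondrial unfolded protein response genes gave 1 of 15 higher, dve-1, 1 lower, hsp-60, and 13 not passing (the same counts adjusted over the list alone). Their median of 0.012 turned to -0.20 with median-of-ratios scaling, and the set test pointed downward (camera adjusted p = 0.131, or 0.0487 with no filter). Lower genes numbered 3 with median-of-ratios and 2 with muscle and neuron scaling, with 1 and 0 higher. hsp-6 was at 373 ± 1.27 and 298 ± 15.4 FPKM (limma adjusted p = 0.103). Of 10 metal-responsive genes, 2 rose, mtl-1 and numr-1, and 8 did not pass (3 adjusted over the list alone, median 0.68, camera adjusted p = 0.241), with 2 higher and 2 lower under muscle and neuron scaling.

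Some genes of detoxification and regulatory families rose, where 14% of all tested genes were called higher. By name stem, ugt, cyp and nhr genes were not enriched among the rises (exact hypergeometric test, adjusted p = 0.132, 0.871 and 0.361). Genes of the gst stem were not enriched either (unadjusted p = 0.316), while the fbxa stem of the F-box list was (adjusted p = 2.57e-10). UDP-glycosyltransferases gave 13 of 50 higher and 37 not passing (18 adjusted over the list alone, median 0.65, camera adjusted p = 0.0222, or adjusted p = 0.468 with an estimated correlation and 0.0975 without RNAi replicate 2, and 0.0636 with muscle and neuron scaling). They gave 9 higher and 1 lower with median-of-ratios and 5 and 2 with muscle and neuron scaling. ugt-66 and ugt-25 rose from 0.41 ± 0.127 to 13.1 ± 2.7 FPKM and from 3.08 ± 0.601 to 22.9 ± 4.4 FPKM. Cytochrome P450 genes gave 8 of 39 higher and 31 not passing (adjusted over the list alone, 14 rose and 1 fell; median 0.67, camera adjusted p = 0.131), among them cyp-13A5, whose call was lost without control replicate 1 at 0.0506. With muscle and neuron scaling 6 of them were higher and 4 lower. Glutathione transferases gave 5 of 34 higher, 1 lower and 28 not passing (the same counts adjusted over the list alone). Their median of 0.24, which turned to -0.26 when scaled on muscle and neuron genes, and the downward set test differed in sign (camera adjusted p = 0.914), and 4 were higher and 6 lower under that scaling. gst-5 rose 4.03-fold to 50.7 ± 1.36 FPKM, and gst-4 was at 16.9 ± 4.8 and 15.8 ± 2.91 FPKM (limma adjusted p = 0.854). Nuclear hormone receptors rose in 29 of 166 cases with 137 not passing (51 adjusted over the list alone, median 0.66, camera adjusted p = 2.4e-05, or adjusted p = 0.468 with an estimated correlation). Receptors called higher numbered 21 with median-of-ratios and 7, with 1 lower, with muscle and neuron scaling. nhr-3 rose from 7.58 ± 1.79 to 36.2 ± 0.523 FPKM. F-box, MATH and BTB genes gave 54 of 215 higher, 1 lower and 160 not passing (adjusted over the list alone, 60 rose and 2 fell). Their median of 0.37 turned to -0.12 when scaled on muscle and neuron genes (camera adjusted p = 0.0305, or adjusted p = 0.806 with an estimated correlation, 0.0651 with no filter, 0.0924 without control replicate 2 and 0.474 without RNAi replicate 1), with 41 higher and 15 lower under that scaling.

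The remaining lists did not pass their set tests. Among 39 lysosome and autophagy genes, 4 rose, 2 fell and 33 did not pass (adjusted over the list alone, 12 rose and 4 fell). Their median of 0.16 turned to -0.059 with median-of-ratios scaling, where 2 were higher and 3 lower (camera adjusted p = 0.914). The autophagy receptor sqst-1 rose from 17.6 ± 3.82 to 158 ± 20.1 FPKM and the cathepsin D gene asp-4 from 79.6 ± 8.68 to 244 ± 17.4 FPKM. Of 22 lipid breakdown genes, 2 rose, 2 fell and 18 did not pass, also when adjusted over the list alone. Their median of 0.028 turned to -0.13 with median-of-ratios scaling, and the set test pointed downward (camera adjusted p = 0.241). With muscle and neuron scaling 0 were higher and 4 lower. acdh-1 was higher at 1254 ± 26.7 against 638 ± 17.1 FPKM and kat-1 lower at 92.2 ± 8.9 against 143 ± 0.728 FPKM. Both calls were lost without either control, at an adjusted p of up to 0.185. Genes induced by DAF-16 gave 2 of 17 higher, mtl-1 and icmt-1, and 15 not passing (adjusted over the list alone, 5 rose and 1 fell). Their median of 0.42 turned to -0.079 when scaled on muscle and neuron genes, where 2 were higher and 3 lower (camera adjusted p = 0.603). Osmotic and epidermal damage genes gave 2 of 12 higher, tsp-1 and nlp-29, 1 lower, hmit-1.2, and 9 not passing (the same counts adjusted over the list alone). The entry behind tsp-1 was written as tpp-1 with tsp-1 as its other name. Whether tsp-1 belongs among osmotic genes is therefore uncertain, and its rise is not evidence of an osmotic response. The hmit-1.2 call was lost without either control, at an adjusted p of up to 0.1. Their median of 0.22, or -0.28 when scaled on muscle and neuron genes, stood against a downward set test (camera adjusted p = 0.914).

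The authors' deposited table of their own comparison listed 8423 genes, of which 397 had an adjusted p under 0.05, 325 higher and 72 lower. Of the calls in the authors' deposited table, 299 of the higher and 68 of the lower genes were also called in the same direction with limma, and 0 were called in the opposite direction. The direction of change was shared by 97.8% of the 8423 genes in the authors' deposited table. The authors' deposited table gave arf-1 a ratio of 0.367 and warf-1 a ratio of 202. Of the 2240 genes called with limma, 769 were not among the genes of the authors' deposited table.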

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

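The settings with 5 FPKM as the minimum, other pseudocounts, whole-number FPKM and scaling on muscle and neuron genes were chosen only after the results were seen, and the other settings before. Of 101 named genes tested, 92 were called, and 40 of these kept the call under every fit, 52 lost it under at least 1 and 0 turned direction. Lower genes numbered 1065 with median-of-ratios scaling, 202 with no filter, 1330 with muscle and neuron scaling and 137 with a 2-fold minimum. With the replicate number as a block, 1353 genes passed, 1182 higher and 171 lower. At an FDR of 0.01, 427 passed, 376 higher and 51 lower. With 1 library left out, which leaves a lone sample assumed to vary like the others, the counts were 515 to 2721, with 450 to 2253 higher and 58 to 468 lower. Under median-of-ratios scaling sams-1, pmt-2 and crh-2, which did not pass, turned to log2 changes of -0.095, -0.027 and -0.18. Under upper-quartile scaling crh-2 turned to -0.031, and under muscle and neuron scaling the 3 turned to -0.37, -0.30 and -0.46. With 1 library left out, sysm-1 ranged from -2.16 to 1.71, sams-1 from -0.23 to 0.47, pmt-2 from -0.020 to 0.40, crh-2 from -0.044 to 0.11, gst-4 from -0.35 to 0.20 and arf-6 from -0.32 to 0.0052.

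Values for lists are adjusted p-values from camera. With median-of-ratios scaling, the p38-dependent list passed at 0.0367 and the COPI list was lost at 0.14. The set direction turned under that scaling for the ARF family (0.872), COPII (0.872), glutathione transferases (0.865), osmotic genes (0.969) and lysosome genes (0.778), none past the threshold. It turned with upper-quartile scaling for the ARF family (0.987) and glutathione transferases (0.995). With no filter, C-type lectins passed at 0.0327 and phosphatidylcholine genes at 0.035, the intracellular pathogen response was lost at 0.0577, and osmotic genes turned (0.836). With 5 FPKM as the minimum, the p38-dependent list passed at 0.0192 and phosphatidylcholine genes at 0.0093, while glutathione transferases (0.837) and osmotic genes (0.519) turned. The ARF family turned with a pseudocount of 0.1 (0.978) and with whole-number FPKM (0.905), as did glutathione transferases with the latter (0.882). Phosphatidylcholine genes passed with a pseudocount of 5 at 0.0426. With the block they passed at 0.0152, as did intestine (0.0438) and muscle genes (0.00712), while the ARF family (0.929) and osmotic genes (0.918) turned. With muscle and neuron scaling, the p38-dependent list passed at 0.0273, the COPI list was lost at 0.857, and COPII (0.499) and lysosome genes (0.304) turned. With an estimated correlation, the called lists of p38-independent, CUB-like, nlp and cnc, intracellular pathogen response, COPI and ER genes all stood at 0.271, so that 0 of the 12 and 0 of the 28 lists passed, against 6 and 16. With fry, 10 and 9 passed, among them the ARF family (0.0224), the p38-dependent list (0.0212), COPII (0.0192) and phosphatidylcholine genes (0.0224), and glutathione transferases (0.0392), osmotic (0.393), lipid breakdown (0.133) and vitellogenin genes (0.934) turned. Heat shock and metal genes (both 0.0256) were gained, and 10 called lists were lost with fry: collagens (0.153), adult epidermis (0.144), germline (0.0561), sperm (0.0591), neurons (0.0561), pharynx (0.0603), pharyngeal cuticle (0.124), ribosomal proteins (0.0591), F-box (0.0623) and histones (0.853). Since fry does not set a list against other genes, it also responds to the median of all genes, 0.21.

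With 1 library left out, the ARF family ranged from 0.435 (without RNAi replicate 1, direction turned to lower) to 0.941, p38-dependent genes from 0.00508 to 0.272, lectins from 0.0398 to 0.435, lysozymes from 0.040 (higher, without control replicate 1) to 0.79 (turned to lower, without control replicate 2), COPI from 0.00924 to 0.0525 and phosphatidylcholine genes from 0.0137 to 0.492. Glutathione transferases ranged from 0.489 to 0.964, osmotic genes from 0.584 to 0.873, lysosome genes from 0.48 to 0.943, vitellogenins from 0.00134 to 0.762 and muscle genes from 0.00159 to 0.923. Within these ranges the direction turned for glutathione transferases and osmotic genes without control replicate 2 or RNAi replicate 1, and for lysosome genes without either control or RNAi replicate 2. It turned for vitellogenins without control replicate 1, and for muscle genes without control replicate 1 or RNAi replicate 2. The cause of these shifts was not tested. Settings planned before the data were examined that need read numbers were not run, namely a Wald test on counts, voom weights, unrounded counts, the trimmed-mean scaling and a minimum count.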

Other observations

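The tests on shared germline RNA for the infection genes and for the uneven split, both tests on warf-1 and the grouping of genes by name stem were chosen only after the results were seen. The tests on scaling and on stage were chosen before. The test on genes staying higher rests on muscle and neuron scaling, a setting chosen after the results were seen. Grouped by the stem of their names, 339 families were tested in each direction (hypergeometric test, Benjamini-Hochberg), and no library was left out in these counts. The test treats genes as independent draws, while members of a family can share reads or move together. Its p-values can therefore overstate the certainty. Transthyretin-related genes rose in 21 of 50 cases with 1 lower (adjusted p = 7.43e-06, median log2 change 0.90), for example ttr-34, from 4.44 to 56.3 FPKM, and ttr-26, from 6.41 to 60 FPKM, while ttr-42 fell from 64.7 to 12.7 FPKM, and 14 were higher when scaled on muscle and neuron genes. F-box genes of the fbxa family rose in 37 of 89 cases with 0 lower (adjusted p = 2.57e-10, median 0.90), for example fbxa-60, from 13 to 127 FPKM, although 6 were lower and 28 higher when scaled on muscle and neuron genes. All 5 pud genes fell (adjusted p = 2.2e-06), but 2 of them, both copies of pud-2.2, are listed with identical values, so they are fewer than 5 measurements. PUF genes of the germline fell in 5 of 8 cases (adjusted p = 5.82e-05), for example puf-5, from 472 to 296 FPKM, and puf-7, from 171 to 102 FPKM. The peroxidase gene skpo-1, named after its value was seen, fell from 169 to 32.2 FPKM.

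The pattern of more rises than falls depended on the scaling. The share of called genes that were higher was 85.6% as deposited, 85.2% with equal totals, 78.9% with upper-quartile and 59.07% with median-of-ratios scaling, so the excess of rises may stem in part from the scaling, though only the last of these 3 scalings brought it under 75%. A lower share of germline RNA as the source of the uneven split also remains open. Germline products did not move together, as sperm genes rose in 34 of 52 cases while oocyte and eggshell genes fell in 20 of 35. A difference in stage was not tested for the split. If shared by both RNAi libraries, it cannot be told apart from the RNAi itself. Scaling on muscle and neuron genes brought the share of higher genes to 52.45%. That scaling lowers the log2 change of every gene alike, so the split would move toward falls whatever the cause, and this cannot decide it. Its log2 offsets also differed within groups, at -0.405 and -0.089 in the controls and 0.123 and 0.371 after RNAi. The spread between replicates therefore changed too, and calls could be gained, as for collagens called higher, from 20 to 61. The muscle list itself differed in its median by 0.51 between the controls and 0.36 between the RNAi libraries. That scaling did not remove all the rises, as 56.31% of the genes called higher were still called higher. These genes were selected for rising in the same libraries. Their share therefore cannot decide whether a lower germline share raised all somatic genes alike as the whole account of the rises. Absolute RNA amounts were not measured, so the split itself has no fixed zero.

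The rise of infection-response genes was weighed against a lower share of germline RNA and against a difference in stage, with several tests of the former tried after the values were seen. Of the 43 genes of 5 infection lists called higher, 79.07% were still called higher after scaling on muscle and neuron genes. Since they were selected for rising in the same libraries, that share cannot decide the cause. The median of all 76 members stayed at 0.88 (95% interval 0.49 to 1.31), above the muscle and neuron genes that set the scale. By list, the median ranged from 0.32 (-0.32 to 1.34) for p38-dependent to 1.69 (0.37 to 2.53) for p38-independent genes. The intervals here come from resampling genes with the libraries held fixed, so they leave out the spread between libraries. They do not settle whether a rise common to all somatic genes was the whole cause. Other choices of genes are less clear, since the infection genes exceeded muscle, neuron, pharynx and intestine genes by 0.84 (0.41 to 1.29), but by 0.37 (-0.082 to 0.84) with epidermis, cuticle and molting genes included, and with lectins and lysozymes added, which did not rise as lists, by 0.19 (-0.15 to 0.44) and -0.28 (-0.64 to -0.014). Stage stays open, as the difference of -0.2005 between the RNAi libraries, although planned before, says nothing of a stage difference shared by both, which cannot be told apart from the RNAi itself. An immune response to loss of ARF-1 is therefore a hypothesis, and its lists lose their calls with an estimated correlation (adjusted p = 0.271).

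The appearance of warf-1 while arf-1 fell was weighed against shared reads and against reads from the RNAi construct. In the RNAi libraries warf-1 stood at no less than 2.676 times arf-1 in FPKM. That ratio alone cannot decide, since reads moved from arf-1 to warf-1 would lower the former and raise the latter. In the controls, where arf-1 was higher, warf-1 stood at no more than 0.834% of it. This argues against reads of arf-1 transcripts being commonly assigned to warf-1 in the controls, though how reads were divided was not examined. Reads from the construct cannot be told apart from transcripts of the gene without the reads themselves. arf-1 was lower in both RNAi libraries by a factor of at least 2.192, which says nothing of a construct holding other ARF sequence. The annotated pseudogene F20D1.5 rose alongside warf-1, from 1.42 to 60.8 FPKM, and sharing of reads between them was not examined. A candidate explanation is that worms raise a second ARF gene when arf-1 is depleted, and this was not tested by any sample in the series.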
